A study of Mus musculus with 5 samples.

How the data were processed

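Gene expression was measured on Affymetrix mouse arrays in 5 samples of sorted mouse embryo cells. Per the labels' protocols, the aorta-gonad-mesonephros (AGM) region of E11.5 embryos was dissected and dissociated with enzymes. Cells positive for VE-cadherin and CD45 were sorted and cultured in medium with fetal serum. They received interferon-alpha (IFNa) at 0.5 ng/ml, or vehicle, for 4 hours. RNA was then amplified with a NuGen kit and labelled with biotin, per the labels' protocols.

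The deposited table held log2 probe set signals, which the authors made with RMA, per the submitters' processing notes. RMA corrects the background of the perfect-match probes, normalizes between arrays and summarises the probes of a probe set on a log2 scale. The RMA software, its version and its settings are not given in the sources used here. The log2 base is that of RMA. The values ran from -1.95 to 15.6, and values below 0 are unusual for RMA, so the step that set the low end of the scale is unknown here and the sizes of differences that reach it are uncertain. The array medians lay between 4.98 and 5.15, so the rows did not share a single distribution across arrays. No detection calls were used, so no probe set could be called present or absent, and the number of arrays limits the precision. A log2 difference between dim values depends on the background step of RMA.

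The table had 20881 rows. The platform annotation paired 17838 rows with 1 gene symbol and 244 rows with several, and 2799 rows had no symbol here. For 17691 of the rows with 1 symbol, the gene identifier was also in the reference gene table (GRCm38.p6), with the same symbol in each case. Of 17756 symbols, 81 had more than 1 row, and for these the row with the highest mean over all arrays was used. The table thus held nearly always 1 probe set per gene. How it was chosen is not given in the sources used here.

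Samples were grouped by the sample titles into IFNa (replicates 1, 2 and 3) and vehicle (replicates 2 and 3). A vehicle replicate numbered 1 was not analysed here. The labels call the replicates biological, and no 2 arrays held identical values. The only comparison was IFNa against vehicle, fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) over all 5 arrays and 17756 genes. All tests were two-sided. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Errors on differences are moderated standard errors (SE).

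Before the data were examined, 23 gene lists with 367 different genes were fixed, of which 333 were measured. The lists cover interferon response, antigen presentation, stem cell regulators, cell cycle, inflammation, cell death, stress and housekeeping genes, and markers of cell types that the sort could hold. Each list was tested with camera in limma at an inter-gene correlation of 0.01, again with an estimated correlation, and with fry. The mean of each list per array was compared with an exact permutation test over the 10 splits of 5 arrays into 3 and 2, whose smallest p is 0.1. Genes were named by a rule fixed at the same time. It took up to 12 called genes with the largest difference in each direction and no overlap between groups, or the 5 with the smallest p where a direction had fewer than 3 such genes. It added up to 4 called members per list, or the member with the smallest p where none was called, and 11 genes fixed by name, of which 3 had no row of their own symbol and were not analysed here.

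The fit was tested on simulated data for IFNa against vehicle, with 20 sets of 17756 genes and 200 genes changed in each. The genes had their real means, and their variances were drawn at random around the fitted mean-variance trend. It recovered 0.224% of genes changed by 1 on the log2 scale, 9.25% of those changed by 2 and 27.6% of those changed by 3. Of 522 calls in all sets, 31 were false. When the 35 measured type I interferon response genes were shifted together, camera called the list in 15 of 20 sets at a shift of 0.5 on the log2 scale and in 20 of 20 at a shift of 1. It called the list in 0 of 20 sets without a shift. These simulated genes were independent of each other, which makes the rates for the list optimistic. The real list also varied less than other genes at its level, which the simulation left out and which acts the other way.

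The alternatives were the mean of all probes of a gene, all rows tested separately, a filter on dim genes, a floor at the 20th percentile, other variance settings (no trend, robust, array weights), repeated quantile normalization and median centring. A replicate block (fixed or random), each array left out in turn, an adjusted p under 0.1 and a minimum of 1.5-fold were also tried.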

Results

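The dataset comprised 5 arrays of cells sorted from the aorta-gonad-mesonephros (AGM) region of E11.5 mouse embryos, the site where the first definitive hematopoietic stem cells (HSCs) arise. The cells carried the endothelial protein VE-cadherin and the pan-leukocyte protein CD45, a combination that includes maturing HSCs. The share of HSCs among the sorted cells was not measured here, so the results are for the sorted cells as a mixture. The IFNa group (n = 3) had received interferon-alpha at 0.5 ng/ml for 4 hours and the vehicle group (n = 2) had not. The series title frames the question as whether interferon-alpha signalling promotes the maturation of these stem cells. Over 17756 genes, Pearson's r between arrays was 0.924 to 0.955 within the groups and 0.892 to 0.933 between them. These correlations are across genes, which are not independent replicates.

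Transcripts of type I interferon response genes did not differ detectably between IFNa-treated and vehicle-treated cells. Of 35 measured members, 0 passed the threshold, 0 did so adjusted over the list alone, and 0 had an unadjusted p under 0.05. The antiviral effector Ifit3 averaged 10.0 in both groups on the log2 scale, with a difference of 0.0014 ± 0.37 (SE). Ifit1 differed by -0.02 ± 0.45, Rsad2 (viperin) by 0.03 ± 0.44 and the interferon-induced GTPase Mx1 by 0.06 ± 0.48. Irf7, the transcription factor that amplifies the type I response, was 7.17 ± 0.43 (SD, n = 3) with IFNa and 6.94 ± 0.20 (SD, n = 2) with vehicle. The difference was within 0.5 on the log2 scale for 29 of the 35 genes. The member with the smallest p was Adar, an RNA-editing enzyme, with a difference of 1.60 ± 1.04 and vehicle arrays at 4.62 and 0.62. Without vehicle replicate 2 its difference was 3.60 with an adjusted p of 0.0164 in limma. Over all alternatives Adar ranged from -0.40 to 3.60, with adjusted p values of 0.0164 to 0.936 in limma. The mean of the list was 7.68 ± 0.23 (SD, n = 3) with IFNa and 7.62 ± 0.19 (SD, n = 2) with vehicle (exact permutation p = 0.7, two-sided, smallest possible 0.1). The median difference of 0.05 was not called by camera (adjusted p = 0.862, limma) and lay between -0.13 and 0.18 over the alternatives. For 10 of the 35 genes the 95% interval of the difference excluded a rise of 1 on the log2 scale. For the other 25 a 2-fold rise was not excluded gene by gene by these intervals. Their moderated SEs draw on the spread of all genes at a like level. The list's median within-group SD was 0.34, against 0.61 for matched random lists, so an interval can be wider than a gene's own arrays imply. Rsad2, for example, had an SD of 0.036 with IFNa and 0.021 with vehicle.

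**Figure D1:**
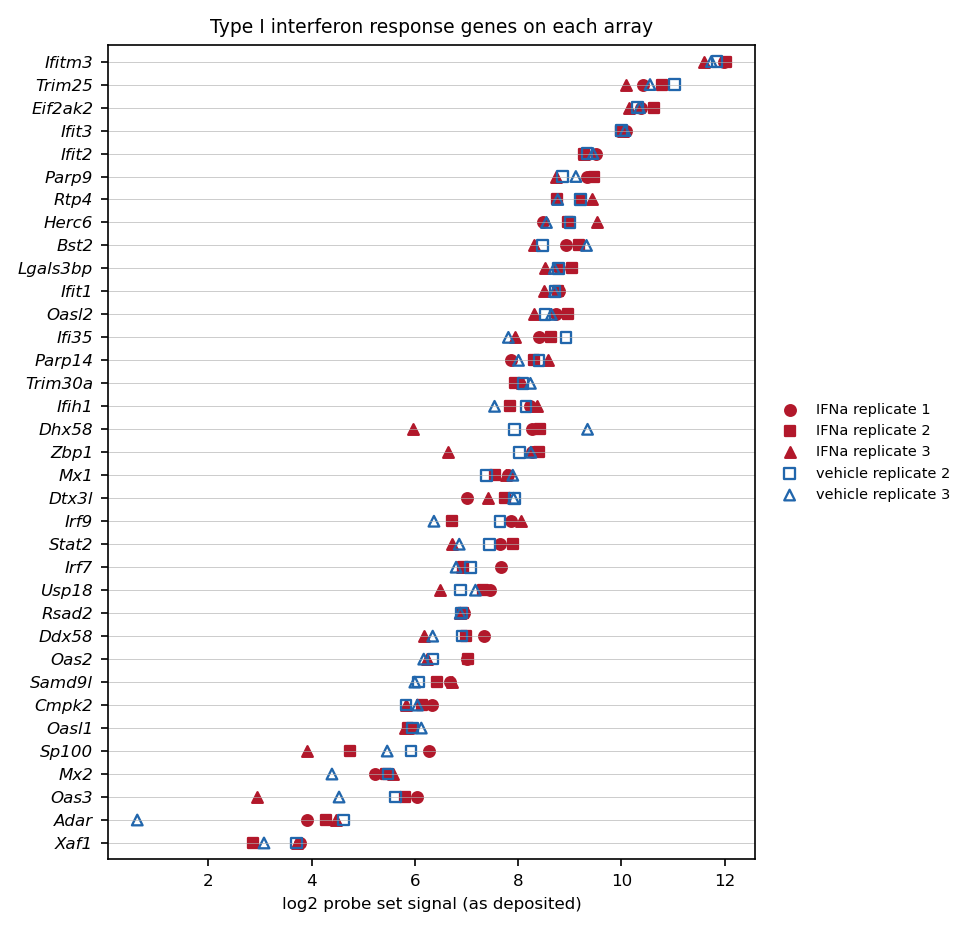
Log2 probe set signal, as deposited, of the 35 measured type I interferon response genes (rows) on each of the 5 arrays (filled red, IFNa; open blue, vehicle; squares and triangles, replicates 2 and 3; circles, IFNa replicate 1). The arrays of both groups overlap for 31 genes and not for 4 (1 higher and 3 lower with IFNa; 11.4%, against 20% by chance), and 29 of the 35 mean differences are within 0.5.

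No gene of the related interferon lists passed the threshold. Among 15 measured guanylate-binding proteins, immunity-related GTPases and IRF1 targets, 0 passed in limma, 0 had an unadjusted p under 0.05, and the median difference was 0.14 (camera adjusted p = 0.862, limma). The chemokine Cxcl10 differed by 0.05 ± 0.26 and the GTPase Irgm2 by 0.14 ± 0.43. Irf8, a myeloid transcription factor, had the smallest p of the list with a difference of 1.70 ± 0.91, which was 3.20 without vehicle replicate 2 and 0.20 without vehicle replicate 3. In the list of MHC class I antigen presentation, 0 of 17 members passed, 2 had an unadjusted p under 0.05, and the median difference was -0.03 (camera adjusted p = 0.971, limma). B2m, the light chain of MHC class I, differed by -0.02 ± 0.17, with an interval of -0.44 to 0.40. H2-K1 (3.51 with IFNa, 3.88 with vehicle) and Tap1 (2.85 and 3.02) lay near or below 3.35, the 20th percentile of all values. Their rows can show little of a response. H2-M3, a non-classical class I gene, was higher on every IFNa array, at 10.8 ± 0.39 (SD, n = 3) against 9.06 ± 1.47 (SD, n = 2), with an adjusted p of 0.448 in limma. Its difference was 2.79 without vehicle replicate 2 and 0.71 without vehicle replicate 3. The other member with an unadjusted p under 0.05, Pdia3, was lower on every IFNa array, with a difference of -1.55 ± 0.63. Both chains of the receptor were measured. Ifnar1 differed by 0.07 ± 0.57 and Ifnar2 by 0.64 ± 0.30, with adjusted p values of 0.986 and 0.545 in limma. In the list of interferon receptors and proximal signalling, 0 of 15 members passed and 0 had an unadjusted p under 0.05 in limma. The median difference was 0.02.

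Genes of the stem cell program did not pass the threshold either. Among 23 measured HSC transcription factors 0 passed in limma and 2 had an unadjusted p under 0.05, with a median difference of 0.16. Runx1, which is required for blood stem cell emergence, differed by 0.43 ± 0.90 and Gata2 by 0.16 ± 0.50. Ikzf1 (Ikaros), with the smallest p of the list, was 11.4 ± 0.75 (SD, n = 3) with IFNa and 9.73 ± 0.0018 (SD, n = 2) with vehicle, an adjusted p of 0.347 in limma. Among 16 surface and self-renewal genes 0 passed and 4 had an unadjusted p under 0.05, and the median difference was -0.19. Cd34 differed by -2.61 ± 0.63 (adjusted p = 0.268, limma), and the stem cell factor receptor Kit by 1.66 ± 0.97. The sort markers also varied between arrays. Ptprc, which encodes CD45, differed by -2.02 ± 0.75 and Cdh5, which encodes VE-cadherin, by -0.95 ± 0.96, with adjusted p values of 0.441 and 0.839 in limma.

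No list of cell type markers was called by camera or fry, and 0 of their 85 measured members passed over all genes in limma, with 11 at an unadjusted p under 0.05. Of 14 macrophage markers, 12 differed by less than 0.5 on the log2 scale, and the median was -0.06. The mean signal of these markers was 10.80 with IFNa and 11.05 with vehicle, the highest of the 23 lists in both groups. HSC surface and self-renewal genes averaged 6.07 and 6.52, and endothelial and arterial markers 5.57 and 5.73. Signals of different probe sets do not give cell shares, so the share of macrophages was not measured. The interferon and stem cell results cannot be assigned to HSCs alone. The macrophage receptor Csf1r read 14.3 to 14.7 over all 5 arrays, and the complement gene C1qb differed by 0.01 ± 0.13. Timd4, a marker of resident macrophages, differed by -2.54 ± 0.91. The 19 endothelial and arterial markers had a median difference of -0.19, and Hey1, a Notch target, differed by 2.73 ± 0.72. The 12 granulocyte and monocyte progenitor markers had a median of 0.34, with Prtn3 (proteinase 3) at 1.15 ± 0.47. The 11 erythroid markers had a median of -0.35. Their member Tfrc, the transferrin receptor, which proliferating cells also express, was 12.3 ± 0.33 (SD, n = 3) with IFNa and 9.39 ± 0.51 (SD, n = 2) with vehicle. It missed the threshold over all genes (adjusted p = 0.0741, limma) and passed adjusted over the list alone, the only member of any list to do so. Without vehicle replicate 2 its adjusted p over all genes was 0.0369 in limma, the lowest of its alternatives, and the highest was 0.319. Megakaryocyte and platelet markers (9 genes, median -0.03) had Vwf at -0.88 ± 0.33, lymphoid markers (9 genes, median -0.18) had Cd3e at -0.30 ± 0.27, and mesenchymal markers (11 genes, median 0.57) had Tagln at -1.73 ± 0.50. Of the mesenchymal markers 6 were above 0 and 5 below, with Acta2, smooth muscle actin, at -2.04, or -1.22 without IFNa replicate 2.

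Proliferation, inflammation, death and stress lists held 0 genes past the threshold over all genes in limma, with 6 members at an unadjusted p under 0.05. DNA replication genes (16, median -0.02) ranged from -1.58 to 1.67, the latter being Rrm1, a subunit of ribonucleotide reductase. Mitosis and G2/M genes (17, median -0.14) included Mki67 at -0.13 ± 0.24 and the spindle factor Tpx2 at -3.25 ± 0.86. NF-kappaB and inflammatory cytokine genes (18, median 0.09) included Birc3 at 1.45 ± 0.69. The p53 target genes (13, median 0.08) and cell death genes (14, median 0.09) included the death receptor Fas at 0.88 ± 0.49 and Casp8 at 0.89 ± 0.41. Immediate early and dissociation stress genes (14, median 0.06) included the heat shock gene Hspa1b at 1.90 ± 0.60. Unfolded protein and amino acid stress genes (11, median -0.03) included Trib3 at -1.03 ± 0.55, and glycolysis genes (12, median 0.04) included Pfkp at 1.17 ± 0.54. Housekeeping genes (10, median 0.02) included Rpl13a at 0.52 ± 0.33. Of the sex-linked genes (4, median -0.14), the X-inactivation transcript Xist and the Y-linked Eif2s3y were above 6.9 on all 5 arrays, and Eif2s3y differed by 0.85 ± 0.71. The median and the mean differed in sign for 3 lists, the DNA replication genes (mean 0.02), the housekeeping genes (mean -0.04) and the sex-linked genes (mean 0.08). Camera gave the direction as up for all 3 without calling any. With each array left out in turn, the median changed sign for 17 of the 23 lists, and the granulocyte and monocyte median ranged from -0.12 to 0.35. Of the 30 genes named by the rule that missed the threshold, 20 moved by over 1.5 times and 7 of these changed sign. Of the 23 lists, camera called 0 and 0 had an unadjusted p under 0.05. The lowest adjusted p was 0.862 with the preset and 0.972 with an estimated correlation, and 0.985 by fry, which asks whether the genes of a list move one way. The lowest adjusted p of fry's test for change in either direction was 0.154.

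**Figure D2:**
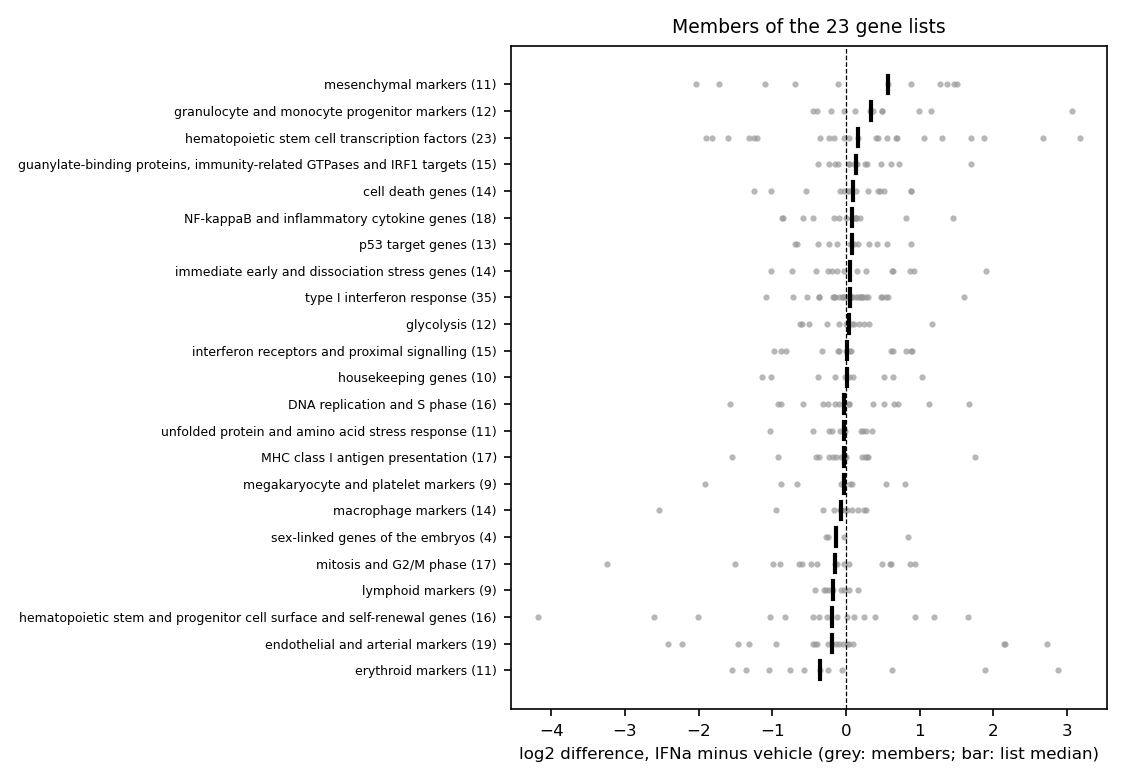
Log2 difference, IFNa minus vehicle, of each measured member (grey dots) of the 23 gene lists fixed in advance, with the list median (black bar) and the number of measured members in parentheses. List medians run from -0.35 for erythroid markers to 0.57 for mesenchymal markers, and members scatter on both sides of 0; with each array left out in turn these medians ranged from -0.75 to 0.08 and from 0.0094 to 0.84.

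Outside these lists, 24 genes passed the threshold, 3 higher and 21 lower with IFNa, and in all 24 the arrays of the groups did not overlap. Taf5, a subunit of the general transcription factor TFIID, rose from 7.13 ± 0.17 (SD, n = 2) to 12.2 ± 0.23 (SD, n = 3), a 33.9-fold difference of 5.08 ± 0.38 on the log2 scale (adjusted p = 0.0116, limma). The lipid hydrolase Abhd4 rose by 4.64 ± 0.49. The atypical cadherin Fat4 rose too, by 4.91 ± 0.49 as deposited, from a dim vehicle mean of 1.52, and by 3.08 ± 0.54 with values floored at the 20th percentile (3.35). All 21 genes that fell lay below that floor on every IFNa array. The sizes of their falls are given as deposited and depend on the background step. The vehicle means of these genes ran from 2.33 to 7.52, so some were below the floor in both groups. The zinc finger gene Zfp418 fell from 6.01 ± 0.25 (SD, n = 2) to 0.36 ± 0.15 (SD, n = 3), with an adjusted p of 0.00154 in limma, and its floored difference was -2.66 ± 0.23. Among the genes that fell were the muscle genes Myh3, embryonic myosin heavy chain (-5.20 ± 0.33), Actc1, cardiac actin (-4.81 ± 0.35), and Myl7, the atrial light chain (-3.36 ± 0.35). The developmental transcription factor genes Dlx2 (-3.84 ± 0.31) and Foxf1 (-3.03 ± 0.23) fell too. So did the purine synthesis gene Gmps (-3.83 ± 0.31), the virus receptor gene Cxadr (-3.72 ± 0.41), the phosphatase gene Cdc14b (-3.68 ± 0.37) and the semaphorin gene Sema4f (-3.46 ± 0.27). The remaining falls of the named set were in Rnf225 (-4.37 ± 0.38), Bnip2 (-4.08 ± 0.26), 4930526L06Rik (-3.87 ± 0.25) and Mfsd11 (-3.49 ± 0.35). The genes Ifit3, Ifit1, Rsad2, Mx1, Cxcl10, Irgm2, B2m, H2-K1, Tap1, Pdia3, Csf1r, C1qb, Acta2, Mki67, Xist, Myl7 and Foxf1 lie outside the naming rule and were chosen after their values were seen.

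**Figure D3:**
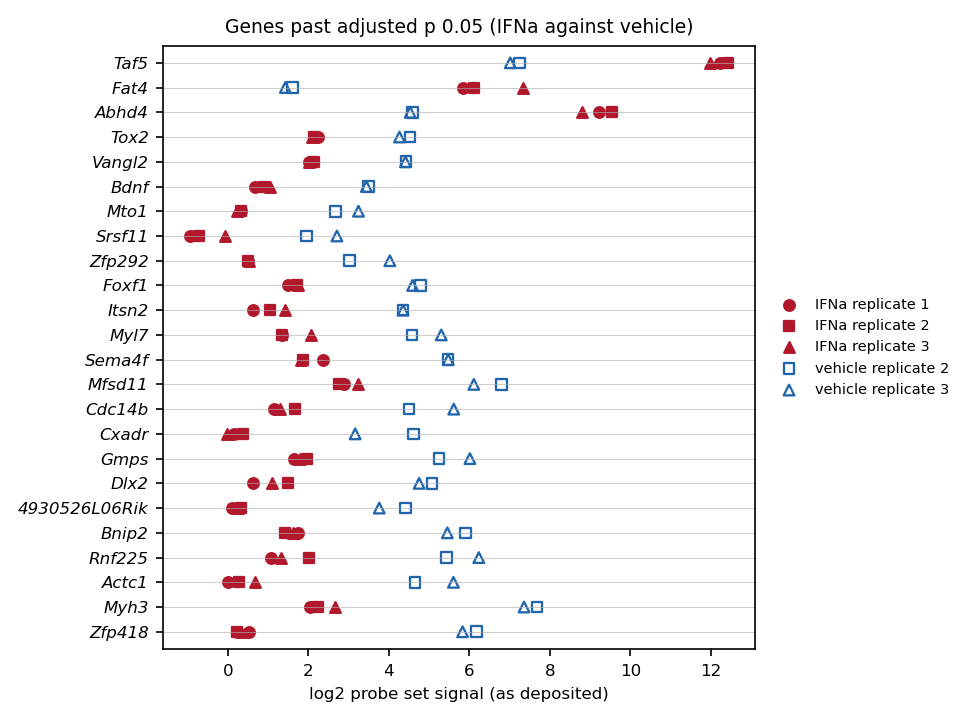
Log2 probe set signal, as deposited, on each array of the 24 genes past an adjusted p of 0.05 (rows, ordered by difference; filled red, IFNa; open blue, vehicle). The 3 genes at the top were higher on every IFNa array, and the 21 below were lower, with IFNa means under 3.

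The probe sets of Fat4, Abhd4, Cxadr and Sema4f are of kinds that can match several transcripts. With values floored at the 20th percentile 0 genes were called by limma in either direction, and 1463 had an unadjusted p under 0.05. Taf5 (5.08, adjusted p = 0.115, limma) and Abhd4 (4.64, adjusted p = 0.141, limma) kept their full difference there, whereas the 19 lower genes that could be tested went from a median of -3.68 to -1.59, with Myh3 at -4.17, Actc1 at -1.78 and Cxadr at -0.63. At an unadjusted p under 0.05 stood 1781 genes, 802 higher and 979 lower, against 887.8 expected by chance, and the groups did not overlap for 25.6% of genes against 20% by chance. The counts moved with single arrays. Without IFNa replicate 1 the counts were 0 higher and 1 lower, without IFNa replicate 2 they were 0 and 9, and without IFNa replicate 3 they were 0 and 0. Without vehicle replicate 2 they were 37 and 144, and without vehicle replicate 3 they were 10 and 140, where the lone vehicle array is assumed to vary like the IFNa arrays.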

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

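The main counts were 3 genes higher and 21 lower with IFNa. Restricting the test to genes above the median level, which removed 22 of the 24 called genes, gave 1 and 0. A floor at the 20th percentile gave 0 and 0 by limma (1463 genes at an unadjusted p under 0.05). There Taf5 and Abhd4 kept their size (5.08 and 4.64), Fat4 was at 3.08, and 19 lower genes ranged from -4.17 (Myh3) to -0.12 (Bdnf). Limma's variance without a trend gave 1 and 2. The cause was not tested for either. An adjusted p under 0.1 gave 19 and 43, and a minimum of 1.5-fold gave 13 lower. Leaving out each array in turn gave 0 to 37 higher and 0 to 144 lower. All 24 called genes kept their sign in each of these refits in which they were tested. The replicate numbers 2 and 3 occur in both groups, and the deviations of same-numbered arrays correlated at 0.0024 and 0.043, with a consensus correlation of 0.118. No label ties them, so they are taken to share only a number. With that number as a fixed replicate block, which leaves 1 residual degree of freedom, 0 and 0 genes were called (1441 at an unadjusted p under 0.05), and with a random block 9 and 27. The mean of all probes, robust variance, array weights, quantile normalization, median centring and all rows tested separately kept both counts within 1.5 times. The 23 lists stayed uncalled by camera under each setting in which it was run, by fry, and with an estimated correlation, with 0 lists called. The median of the type I interferon list ranged from -0.13 to 0.18 over 13 settings. The robust and random block settings were not run for the lists. Most called genes were dim, which is a limit of the calls, but it was not tested as the cause of the lost ones.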

Other observations

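The tests of labels, treatment, floor, vehicle level, spread and cardiac genes, and the lists of Schlafen, interferon and muscle genes, were chosen after the results they concern were seen. Among genes that missed the threshold, Slfn3 of the Schlafen family, whose members include interferon-induced genes, differed by 5.14 ± 0.67 on the log2 scale (adjusted p = 0.0714, limma). No member passed in limma, and the others went both ways. The 8 measured members had a median difference of -0.0075, with Slfn10-ps at 1.32 ± 0.48 and higher on every IFNa array (adjusted p = 0.435, limma), Slfn2 at 0.10 ± 0.34, Slfn5 at -0.01 ± 0.47 and Slfn8 at -0.0020 ± 0.45. Schlafen genes have near-identical copies, so the signal of Slfn3 is uncertain. Of 7 measured interferon genes 0 passed, and Ifnb1 differed by 0.56 ± 0.52, or -0.09 without vehicle replicate 2 and 1.22 without vehicle replicate 3. Other large differences that missed the threshold were Vps52, a subunit of vesicle-tethering complexes, at 5.35 ± 0.65, and Nt5dc1 at 4.21 ± 0.52. The chemokine receptor gene Cxcr4, which homes stem cells to their niche, differed by -4.18 ± 1.25, and the homeobox gene Hoxa9 by 3.18 ± 0.93. For 31 of the genes named outside the rule each array was left out in turn. With all arrays 28 of them missed the threshold. When an array was left out, 20 of these moved by over 1.5 times and 11 changed sign. Of 3043 rows without a single gene name, 4 passed when all rows were tested, all lower with IFNa.

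The type I interferon response genes did not part the groups, whereas 24 other genes passed the threshold in limma. Those calls changed with the settings and when single arrays were left out. Labels exchanged among these arrays, or a single wrong label, are argued against as hiding a list mean difference of 1 log2 or more. A smaller hidden difference stays open. Over the 10 splits into 3 and 2 arrays Ifit3 differed by -0.07 to 0.07, Rsad2 by -0.05 to 0.05 and Mx1 by -0.28 to 0.35. These genes were chosen after their values were seen, and Ifit3 and Rsad2 hardly varied over the 5 arrays. Their ranges therefore cover these genes only and not the rest of the list. The largest difference of the list mean over these splits and the 5 single arrays was 0.342. It arose in the split that an exchange of IFNa replicate 3 and vehicle replicate 2 would give. That split called 0 genes and parted 15 by at least 3 on the log2 scale (24 and 143 as labelled). Among 10 splits any can be the highest by chance, so these counts cannot tell which labels are right. Ifit3, Rsad2 and Mx1 differed by -0.02, 0.05 and -0.26 in that split, but the median of the 35 members was 0.20 (0.05 as labelled). In both cases 2 members differed by 1 or more in either direction. An exchange of these arrays that hides a small difference therefore stays open. Camera called the list in 2 of the 10 splits, neither the real one, with its lowest adjusted p (0.00264, limma) in this split, which is no test since the split was picked as the most extreme. Probe sets at the floor of the scale are argued against, since 5 of the 35 members had a mean under the median of all genes. The list also varied less than other genes: its median within-group SD was 0.34, against 0.61 (0.46 to 0.79 in 95% of cases) for 10000 random lists matched on mean level. Also open are the same treatment in all 5 arrays (the list mean had a range of 0.429 over them), a response already present in the vehicle cells (their mean of 7.62 cannot be set against cells never cultured, not analysed here) or no response in either group.

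The genes called lower with IFNa lay at the low end of the scale on the IFNa arrays. A difference in the distribution of low values between arrays is argued against as the whole cause, since 18 of the 21 stayed called after quantile normalization. The median difference over all 21 was -3.49 before (median SE 0.30) and -3.35 after (median SE 0.27). Quantile normalization keeps each gene's rank within an array, so it does not test whether the low values themselves are reliable. With values floored at the 20th percentile, 0 lower genes were called by limma. Taf5, which kept its difference of 5.08 there, was not called either (adjusted p = 0.115, limma). The lost calls alone are therefore no evidence about the low values. Chance loss of transcripts in amplification stays open: 60 genes were lower and 83 higher by at least 3 on the log2 scale in the real group of 3, against at most 37 lower and 24 higher in other splits, and 0 other splits reached the total of 143, but among 10 splits any can be the highest by chance, so the bound set for this test was too weak. The 10 splits are likewise too few for a share under 0.05 for the calls, with 24 genes in the real split, 1 of 10 with as many, and 0 in the highest other. A difference in handling that followed the groups may remain, since the labels give no batch, and an effect of IFNa on these genes stays open too, untested.

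Actc1, Myl7 and Myh3 would fall together if the vehicle samples held muscle cells, which the sort for VE-cadherin and CD45 should remove. The tests leave this open. The 20 other cardiac and skeletal muscle genes had a median difference of -0.45 (bootstrap interval -0.75 to -0.14), but the list lacks the called muscle genes and 15 of its members lay under the median of all genes, so the bound of -1 set for it excludes nothing. The 11 cardiac genes among them had a median of -0.29 (interval -1.74 to 0.20), with 7 lower and 4 higher, such as Mybpc3 at 0.67, Actn2 at 0.37 and Myh7 at 0.20. Myl4 differed by -1.74 ± 0.46, Myh6 by -2.58 ± 0.78 (-1.10 without vehicle replicate 2 and -4.06 without vehicle replicate 3) and Nppa by -1.55 ± 0.46 (-0.75 and -2.35), none past the threshold with all arrays, so cardiac cells in the vehicle samples may be a source but are not shown.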
